A study of Homo sapiens with 4 samples.

How the data were processed

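Total RNA extracted with Trizol from 4 samples of MCF7 cells was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. Each sample filled 1 group, so there were no replicates. Values were deposited by the authors as 1 table of log2 expression per probe, summarised by RMA per the submitters' processing notes, which name no version. RMA corrects background, normalizes by quantiles and summarises probes on a log2 scale, which compresses differences of dim genes. Which arrays were normalized together, the probe filter and the genome build are not given in the sources used here. Column medians lay between 5.24 and 5.31. Of the untreated values, 99.8% were written with over 5 decimals and none of the others were, so the untreated column was processed or exported apart from the rest, and levels set across it and the PMA arrays carry that limit. No scanner files, detection calls or array dates were used here.

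The table held 19954 probes. The platform annotation gave 1 gene symbol for 17581 of them, several for 1450 and none for 923, and probes of the last 2 kinds were not named. Symbols were updated through Entrez identifiers in a RefSeq gene table of assembly GRCh38.p14, which held 17560 of the single-gene probes, and no coordinates were taken from it because the build of the array annotation was not stated. This left 16947 genes. For the 479 with over 1 probe, the probe with the highest mean over the 4 arrays was used. AKR1C2 and other members of near-identical families may share signal. All 4 columns of values were mapped to their samples by the sample accession that heads each.

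Differences were taken as 1 array minus another on the log2 scale, for 4 comparisons: unsorted PMA minus untreated, CD44-high CD24-low minus pooled other fractions, and each sorted sample minus untreated. A gene was kept in a comparison where the higher of its 2 values reached the 40th percentile of all values in the table, a log2 level of 4.85. Kept genes were counted as higher or lower at a difference of 1.0 in log2, a fold of 2.0. With 1 array per group no test was run, and the number of arrays limits the precision. Between the 2 most similar arrays, the pooled fractions and the unsorted PMA cells, the SD of the differences over kept genes was 0.18 and 1 of 10625 genes was past 2-fold. That SD was 0.37 between the sorted samples and 0.69 between unsorted PMA and untreated cells.

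The design, the alternatives, the rule for named genes and 26 gene lists were set before the data were examined. Named were the 12 genes furthest each way in the first 2 comparisons and the 5 furthest each way in the other 2, CD44 and CD24 throughout, up to 4 members of each described list with the largest difference, and the 5 furthest each way in the sorting check. The 5 genes named as higher in both the PMA and the fraction comparison and the silent families were chosen after the values were seen. The lists were the sort markers, mesenchymal, epithelial, luminal, estrogen receptor target, basal, breast stem cell, AP-1, NF-kB, protease, integrin, protein kinase C, cell cycle, p53, interferon, hypoxia, unfolded protein, cholesterol, heat shock, ribosomal, oxidative phosphorylation, epigenetic, leukocyte, fibroblast, endothelial and housekeeping genes. Some genes stand on over 1 list, and listed genes without a single-gene probe were not analysed here. A list with at least 3 kept members was described by its median and by the percentile of that median among 10000 random lists of the same size, drawn within 20 bins of mean expression.

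For the sorting check, genes past 2-fold between the sorted samples were asked whether the unsorted level lay between theirs. Overlaps of gene counts were set beside the product of the list sizes over the number of genes measured in both. For comparisons that share the untreated array, 100 sets of unchanged arrays were simulated with the noise seen between the pooled fractions and unsorted PMA cells. Silent families were olfactory, taste and vomeronasal receptors, keratin-associated proteins and beta-defensins, 282 genes with a median level of 3.42 in untreated cells. They were taken as silent without detection calls for these cells. A fold whose lower level was under their 95th percentile on that array is given as a bound, the brighter level over the higher of the dim level and the silent-family median, and leaves out array noise.

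The alternatives were no filter on dim genes, a filter at the 60th percentile (5.70), the mean of all probes of a gene, a 3-fold threshold, each array centred on its median, quantile normalization, cyclic loess, and all probes whether named or not. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 for cyclic loess. The counting and list steps were tested on simulated data for the comparison of the sorted samples, with the noise seen between the pooled fractions and unsorted PMA cells. All of 100 genes changed by 3.0 in log2 (100.0%) and 98.0% of 100 genes changed by 1.5 were recovered with the right sign, and 0 of 10396 unchanged genes passed 2-fold. Those are the 2 most similar arrays, so the 0 checks the steps and gives no rate of false calls for the real arrays. Of 200 unchanged lists, 4.50% fell outside the central 95% of random lists, and a 20-gene list shifted by 0.5 lay at the 100.0th percentile.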

Results

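Gene expression was measured in MCF7, an established human breast cancer cell line of luminal, estrogen receptor positive type, on 4 Affymetrix arrays. PMA is a phorbol ester that activates protein kinase C, and treated cells received 0.65 ng/ml for 60 h. The 4 groups were untreated cells, unsorted PMA-treated cells, PMA-treated cells sorted by flow cytometry for high CD44 and low CD24 surface staining, and a pool of the remaining PMA-treated CD44 and CD24 staining classes. The CD44-high CD24-low stain is widely used to mark breast cancer stem-like cells, and the submitters titled the pooled sample as not being cancer stem cells. Each group had 1 array and no replicates, so no difference below carries an error or a test, and genes were counted by size alone. Median log2 expression over all probes was 5.25 in untreated cells, 5.30 in unsorted PMA cells, 5.31 in the pooled other fractions and 5.24 in the CD44-high CD24-low fraction. The untreated values were written with up to 9 decimals and those of the 3 PMA arrays with at most 5, and whether the 4 arrays were normalized together is not known.

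The first comparison, unsorted PMA cells against untreated cells, addressed what PMA did to the whole culture. Of the measured cell cycle genes 29 of 35 were 2-fold lower, of the interferon response genes 16 of 23 were 2-fold higher, and both sort markers had higher transcript levels in the PMA-treated cells. FBXO32, a ubiquitin ligase subunit known from muscle atrophy, had the largest measured difference, at least 35.4-fold higher (log2 8.57 against 3.27). ITGB6, the beta subunit of an epithelial integrin that activates TGF-beta, was 26.0-fold higher, and IFIT1, an antiviral effector induced by interferon, was at least 23.0-fold higher. DIAPH3, a formin that assembles actin, had a log2 difference of -3.94 and was at least 14.5-fold lower. CD44 was 6.12-fold higher (9.32 against 6.71) and CD24 was 4.13-fold higher (10.29 against 8.25).

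Of 11072 genes bright enough in either sample, 452 were at least 2-fold higher and 761 at least 2-fold lower in unsorted PMA cells. At 4-fold the counts were 49 higher and 173 lower. A fold is given as at least N-fold where the lower level was under the 95th percentile of silent gene families on its array (5.75 in untreated and 6.47 in unsorted PMA cells), since such a level is not shown to lie above background, and log2 differences are as measured. Where the lower level lay above the silent-family median, that fold equals the measured one. The words at least, here and below, allow for background only. They leave out noise between arrays and set no lower limit on the true fold. Silent-family genes differed by up to 1.98 in log2 between unsorted PMA and untreated cells (SD 0.51). For some genes named below both levels were under that percentile on their arrays, so detection is not shown in either sample. In this comparison MMP13, DUSP4, DUSP5, ALDH1A3 and TET1 were among them. Among 282 genes of families taken here as silent, such as olfactory and taste receptors, 13 were 2-fold higher and 6 were 2-fold lower, and none reached 4-fold. Their silence in these cells was assumed, and some members may be expressed. Of the 58 that passed the brightness filter 16 were past 2-fold (27.6%), against 11.0% of all kept genes. The filter goes by the higher value and so favours silent genes that differ, but a 2-fold difference of a dim gene from the untreated array does not by itself point to PMA. The other genes among the 12 highest were DDX60 (log2 difference 3.75), OAS1 (3.65), IFIH1 (2.95) and RIGI (2.92), which belong to the antiviral RNA response, the small GTPase GEM (3.40), PHLDA1 (2.96), the retinoic acid induced receptor GPRC5A (2.92), the coagulation inhibitor TFPI (2.92) and KLHL24 (2.82). The remaining lowest genes were NDC80 (-3.50), SPC25 (-3.26), SPDL1 (-3.18), KIF11 (-3.35), KIF15 (-3.19), ASPM (-3.21), HMMR (-3.18), the checkpoint kinase TTK (-3.17), the meiotic recombination factor MND1 (-3.54), ARHGAP11A (-3.18) and the imprinted gene PEG10 (-3.19). In unsorted PMA cells DIAPH3, SPC25 and KIF15 lay under the silent-family median of 3.37, so their order is not settled.

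The cell cycle and replication list stood furthest from the other genes in this comparison. Of its 35 measured members, 29 were 2-fold lower and none was higher, with a median log2 difference of -1.99, below all 10000 random lists of matched expression. CDK1 (-3.16) and the proliferation marker MKI67 (-2.78) were among its largest members. A percentile among random lists describes these arrays and is not a test of PMA. Of 23 interferon response genes, 16 were 2-fold higher and none lower, with a median of 1.68, above all random lists. Plasminogen and matrix protease genes had a median of 1.03 (7 of 14 higher), also above all random lists, led by the collagenases MMP13 (2.20) and MMP1 (2.10), the protease inhibitor TIMP1 (1.84) and the cathepsin CTSL (1.52). Integrin and adhesion genes had a median of 0.83 (7 of 18 higher), again above them all, with ITGAV, the partner of ITGB6, at 1.74 and ITGA2 at 1.61.

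**Figure D1:**
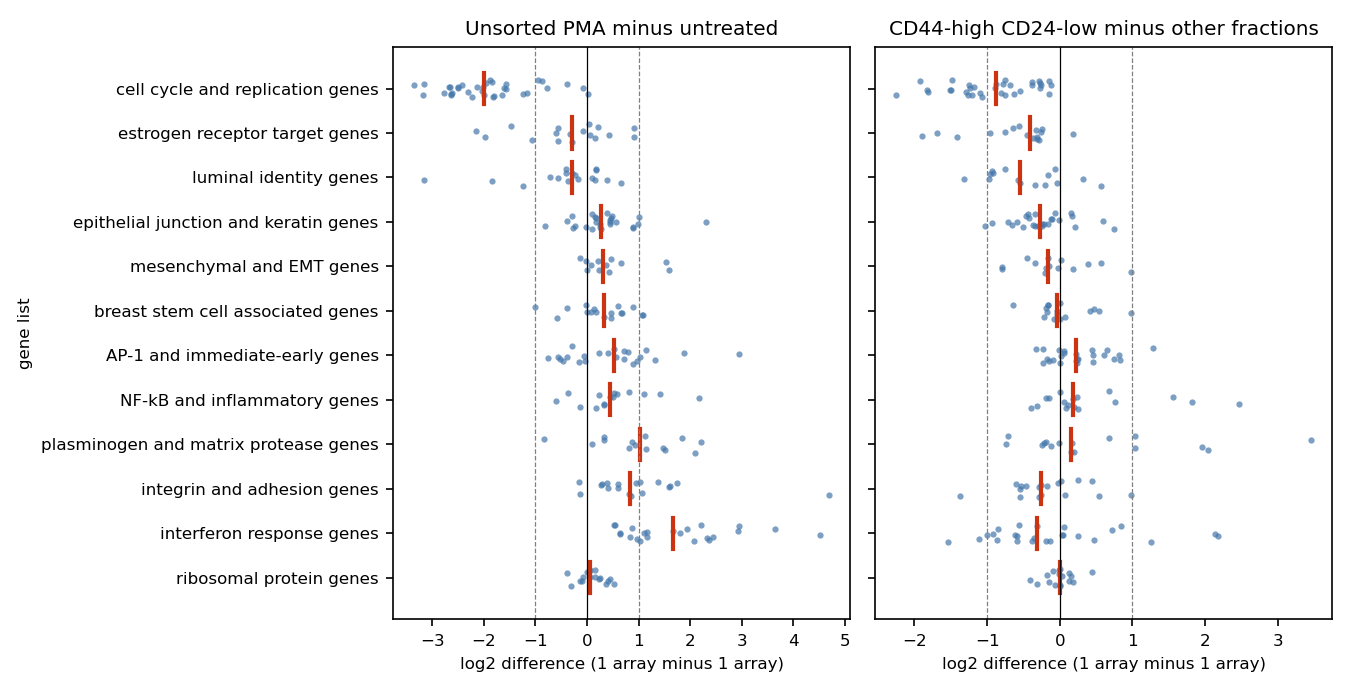
Log2 difference of each measured gene (dots) of 12 fixed gene lists in unsorted PMA minus untreated cells (left) and in the CD44-high CD24-low fraction minus the pooled other fractions (right), with the list median as a red bar and dashed lines at a 2-fold difference. Each difference is 1 array minus 1 array. Interferon genes lay above 0 on the left (median 1.68) and spread to both sides on the right (median -0.31), while the cell cycle median lay below 0 in both (-1.99 and -0.88).

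Genes known to be induced by PMA through AP-1 and immediate-early signalling had a median of 0.53 (5 of 23 higher, 99.99th percentile). Their largest members after PHLDA1 were the MAP kinase phosphatases DUSP4 (1.88) and DUSP5 (1.14) and the transcription factor ETS2 (1.32). No member was 2-fold lower, but EGR1 was 1.44-fold lower and EGR3 differed by -0.56. The p53 and growth arrest list had the same median of 0.53 (5 of 17 higher), and its largest members were TP53INP1 (2.16), GADD45A (1.25) and the cyclin-dependent kinase inhibitors CDKN1A (1.86) and CDKN2B (1.30). NF-kB and inflammatory genes had a median of 0.44 (3 of 15 higher, 0.27 to 0.96 under 6 other settings), with the chemokine CCL5 at 2.18 and LCN2 at 1.42. Estrogen receptor targets had a median of -0.30 (4 of 17 lower, none higher), with CXCL12 at -2.14, MYB at -1.98 and PGR, the progesterone receptor, at -1.48. In the luminal identity list (median -0.28, 3 of 17 lower), the estrogen receptor gene ESR1 differed by -1.84 and BCL2 by -1.25. AGR3 differed by -3.17, with a level of 2.70 in unsorted PMA cells, under the silent-family median. The percentiles of these last lists were 1.32 and 3.41, the luminal one inside the central 95% of random lists, and both crossed its edge under some of these settings.

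Breast stem cell associated genes had a median of 0.33 (98.0th percentile), which ran from 0.11 to 0.53 under 6 other settings (84.8th to 99.5th percentile). Of its 17 members ALDH1A3 (1.08, or 0.89 as the mean of its probes) and ITGA6 (1.08) were higher, and the Wnt receptor FZD7 was lower (-1.01, or -0.96 after quantile normalization). Mesenchymal genes had a median of 0.31 (2 of 12 higher, 96.7th percentile), namely ITGA5 (1.59) and TGFB2 (1.54). Epithelial junction and keratin genes had a median of 0.26 (2 of 26 higher, 98.9th percentile), among them the tight junction gene CLDN1 (2.30). Medians of the basal, hypoxia, unfolded protein and cholesterol synthesis lists were 0.57, 0.27, 0.33 and 0.27, with 1, 1, 1 and 2 members 2-fold higher and none lower. The protein kinase C isozymes, the family PMA binds in part, had no member past 2-fold and a median of -0.32 (-0.37 to -0.18 under 6 other settings), with PRKCA at -0.55. Epigenetic regulators and oxidative phosphorylation genes had medians of -0.19 (-0.08 after quantile normalization) and -0.18. Of the epigenetic list 5 of 21 members were 2-fold lower, led by the demethylating enzyme TET1 (-1.36), SUZ12 (-1.31), the methyltransferase DNMT1 (-1.29) and EED (-1.21), and of the other 1 of 20, UQCRB (-1.16). Ribosomal protein, housekeeping and heat shock genes had medians of 0.06, 0.05 and 0.01, whose sign differed between settings, and 2 of 19 heat shock genes were 2-fold higher. B2M (1.70), which is also part of the antigen presenting complex, was the only housekeeping gene past 2-fold.

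Markers of cell types other than epithelium were mostly below the brightness filter. The 3 leukocyte markers that passed it were TYROBP (0.76), LAPTM5 (0.71) and CD68 (0.19). Of the fibroblast markers COL1A1 differed by 0.38 and COL3A1 by -0.13, and the 5 endothelial markers had a median of 0.14 (0.06 to 0.45 under 6 other settings) with ENG, which epithelial cells can also express, at 1.28 and ESAM at -0.91.

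The comparison of the CD44-high CD24-low fraction with the pooled other fractions asked how the cells sorted by that stain differed within the same PMA treatment. It does not use the untreated array. In the fraction 15 of 33 cell cycle genes and 3 of 16 estrogen receptor targets were 2-fold lower, and 5 of 16 matrix protease genes were 2-fold higher. MMP1, interstitial collagenase, was at least 11.0-fold higher (9.11 against 5.64), and the endoplasmic reticulum chaperone CLGN was at least 8.77-fold higher. The DNA topoisomerase TOP2A had the lowest log2 difference, -2.25, and was at least 4.77-fold lower. At the transcript level the sort markers differed less than 2-fold, with CD44 1.80-fold higher (10.01 against 9.16) and CD24 at -0.43, or 1.35-fold lower (9.97 against 10.40).

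Of 10637 kept genes, 87 were 2-fold higher and 133 were 2-fold lower in the fraction, and 8 and 3 passed 4-fold. With each array centred on its median the counts were 113 and 115, so that the share of higher genes was 49.6% in place of 39.5%. Only 1 of the 282 silent-family genes was past 2-fold here. The highest genes after MMP1 and CLGN were the ketosteroid reductase AKR1C2 (2.66), the chemokines CCL5 (2.47) and CCL22 (1.88), the interferon-induced HERC5 (2.18) and IFIT2 (2.13), S100P (2.07), the stromelysin MMP10 (2.04), the protease inhibitor SERPINE2 (1.96), the glutaredoxin GLRX (1.95) and the pro-apoptotic PMAIP1 (1.87). AKR1C2 has near-identical family members that its probes may not separate. The lowest after TOP2A were apolipoprotein APOD (-2.20), the fatty acid elongase ELOVL2 (-2.12), the replication and mitosis genes PCLAF (-1.99), RRM2 (-1.93), MELK (-1.90), MKI67 (-1.83), DLGAP5 (-1.83) and PBK (-1.82), PGR (-1.90), the ectonucleotidase NT5E (-1.87) and FREM2 (-1.81).

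Cell cycle and replication genes again lay lowest, with a median of -0.88, 15 of 33 members 2-fold lower and none higher. The luminal identity list had a median of -0.55 (-0.32 with no filter on dim genes), below all random lists, with 1 of 15 members 2-fold lower, ESR1 at -1.32, and CA12 at -0.98 and the prolactin receptor PRLR at -0.96. Estrogen receptor targets had a median of -0.41 (3 of 16 lower, 0.01st percentile), in which GREB1 differed by -1.69, the cathepsin CTSD by -1.41 and the cyclin CCND1 by -0.96 beside PGR. Epithelial junction and keratin genes had a median of -0.27 (0.10th percentile), with KRT19 (-1.03) 2-fold lower and KRT8 at -0.94. KRT19 fell under 2-fold with each array centred on its median. Integrin and adhesion genes had a median of -0.26 (0.60th percentile), with L1CAM at -1.38 but ITGA5 at 0.98.

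Interferon response genes went both ways in the fraction. Their median was -0.31 (0.03rd percentile) and their mean -0.08, and of 25 measured members 3 were 2-fold higher and 2 were 2-fold lower. Higher were HERC5, IFIT2 and OASL (1.26), and IFI44L (-1.54) was lowest. The protease list had 5 of 16 members 2-fold higher and none 2-fold lower, including MMP13 (1.04), with a median of 0.16 (98.7th percentile) that ran from 0.11 with no filter on dim genes to 0.85 under the 60th percentile filter. Among NF-kB and inflammatory genes (median 0.18, 0.09 to 0.25 under 6 other settings, 99.6th percentile), 3 of 17 were higher, CCL5, IL6 (1.81) and LCN2 (1.56). IL6 lay under the silent-family median in the pooled fractions (3.15 against 3.35) and under the silent-family 95th percentile in the fraction (6.46). Neither its detection nor the size of its difference is settled. AP-1 and immediate-early genes had a median of 0.22 (99.99th percentile) with ETS2 (1.29) past 2-fold, and hypoxia genes had a median of 0.28 (99.97th percentile) with VEGFA (1.17) past 2-fold. The unfolded protein list had a median of 0.01, or up to 0.20 and the 98.8th percentile under other settings, and 3 of its 18 members were higher, DNAJB9 (1.54), DDIT3 (1.41) and the cystine transporter SLC7A11 (1.14), while PDIA4 differed by -0.99.

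Of 29 listed breast stem cell associated genes 16 were kept, and none of these was past 2-fold in the fraction. The list's median was -0.03 and its mean 0.05, which differ in sign. Its largest member was KLF4 (0.98, past 2-fold with each array centred on its median), followed by JAG1 (-0.64). Of 30 listed mesenchymal genes 14 were kept, and none was past 2-fold either (median -0.16, 10.3rd percentile, -0.25 to -0.05 under 6 other settings). Members went both ways, with ITGA5 and TGFBI at 0.98 and 0.56 and FN1 and THBS1 at -0.80 and -0.79. ITGA5 passed 2-fold with each array centred on its median. The heat shock and cell handling list, which responds to sorting and dissociation, had a median of 0.18 (99.6th percentile, down to the 95.5th under other settings), no member past 2-fold, and HSPB1 at -0.95 and EGR1 at 0.75 as its largest. For p53, oxidative phosphorylation, epigenetic and housekeeping genes the medians were 0.07, -0.19, -0.10 and -0.10, all but the second moving over 1.5 times with the setting, and the p53 target ZMAT3 (1.32) and the lysosomal enzyme GUSB (-1.19) were past 2-fold. The basal, protein kinase C, cholesterol synthesis, ribosomal and endothelial lists had medians of -0.15, -0.01, -0.07, 0.00 and 0.03, and the sign of each differed between settings. Of the leukocyte and fibroblast markers, CD68 differed by 0.84, TYROBP by -0.16, COL1A1 by 0.19 and COL3A1 by -0.15.

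**Figure D2:**
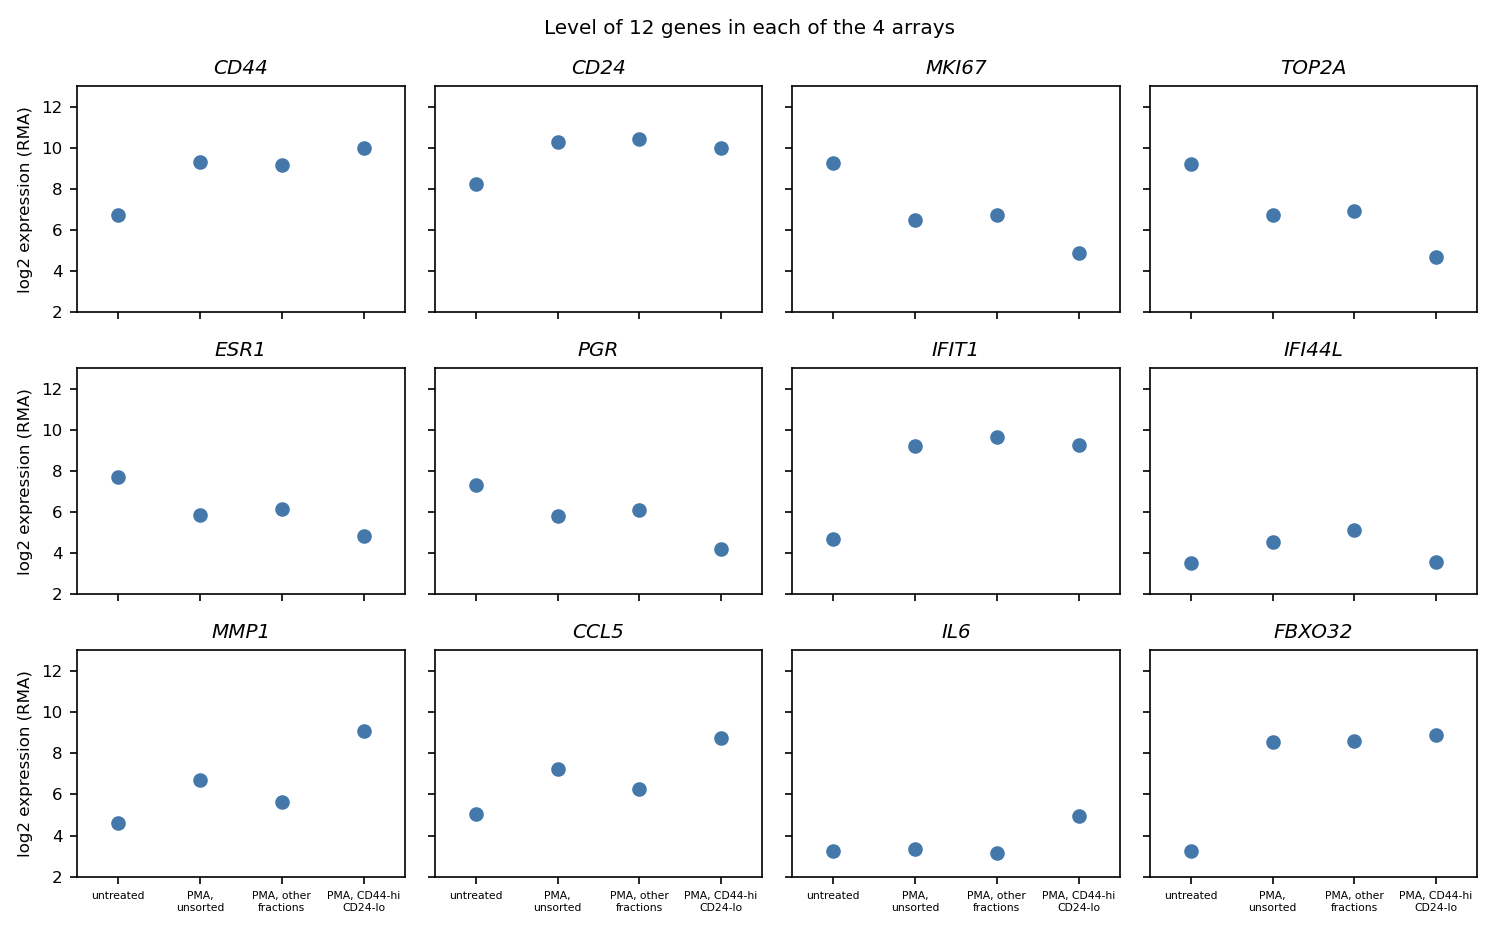
Log2 expression of 12 genes in each of the 4 arrays, 1 dot per array. CD24 was 9.97 in the CD44-high CD24-low fraction and 8.25 in untreated cells, MKI67 was 9.28 in untreated cells, 6.72 in the pooled fractions and 4.89 in the CD44-high CD24-low fraction, and MMP1 was highest in that fraction (9.11).

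The PMA comparison and the fraction comparison share no array, and they were set against each other over 10408 genes measured in both. Of the 545 genes 2-fold lower with PMA, 74 were 2-fold lower again in the CD44-high CD24-low fraction, where independent lists would share 6.91, and none was 2-fold higher. Of the 448 genes 2-fold higher with PMA, 29 were higher again (3.31 for independent lists) and 13 were lower (5.68). MMP1, MMP13, CCL5, IFIT2 and HERC5 were 2-fold higher in both comparisons. Over all these genes the differences were nearly uncorrelated (Pearson r = 0.14, Spearman rho = 0.02 across genes, which are not independent replicates).

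**Figure D3:**
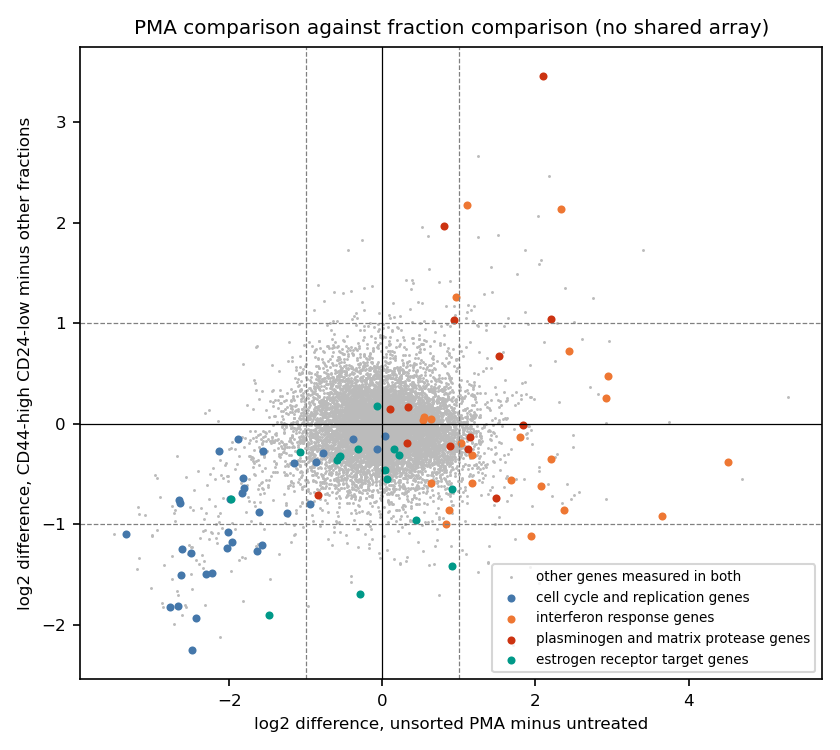
Log2 difference of each gene in unsorted PMA minus untreated cells (horizontal) against the CD44-high CD24-low fraction minus the pooled other fractions (vertical), with dashed lines at a 2-fold difference and 4 gene lists in colour. Cell cycle genes lay mostly toward the lower left, with 29 of 35 2-fold lower in the first comparison and 15 of 33 in the second. Of genes of any kind, 74 were 2-fold lower in both comparisons. Interferon genes lay on the right on both sides of 0.

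Each sorted sample was also compared with untreated cells, which asks how far either population stood from them. The untreated cells were not sorted and their culture time is not given in the sources used here. PMA treatment, staining class and sorting itself are therefore not separated in these comparisons. In the CD44-high CD24-low fraction 31 of 35 cell cycle genes were 2-fold lower and 16 of 23 interferon response genes were 2-fold higher than in untreated cells. FBXO32 was at least 43.7-fold higher, IFIT1 at least 23.8-fold, MMP1 and GEM each at least 22.8-fold, and ITGB6 was 20.6-fold higher. PBK, MND1, TOP2A, CENPF and DTL, all linked to cell division or recombination, differed by log2 -4.72, -4.56, -4.54, -4.47 and -4.45, MND1 with a level under the silent-family median in the fraction. CD44 was 9.83-fold higher and CD24 was 3.29-fold higher than in untreated cells, although this fraction was sorted for low CD24 staining. Of 10997 kept genes 490 were 2-fold higher and 893 were lower, and 79 and 240 passed 4-fold. Silent-family genes past 2-fold numbered 15 higher and 3 lower of 282, or 15 (24.2%) of the 62 that passed the filter against 12.6% of all kept genes.

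The cell cycle list had a median of -2.96 in this comparison, and MKI67 differed by -4.39. NF-kB and inflammatory genes had a median of 0.44 (5 of 18 higher, up to 1.63 under the 60th percentile filter), with CCL5 at 3.68 and LCN2 at 2.51. Interferon genes had a median of 1.73 (16 of 23 higher), proteases 1.05 (8 of 16 higher, 1 lower, up to 1.80 under that filter), p53 and growth arrest genes 0.77, hypoxia genes 0.62 and AP-1 genes 0.59 (7 of 25 higher). Luminal and estrogen receptor target lists had medians of -0.66 and -0.62, each with 5 of 17 genes lower, and ESR1 differed by -2.86 and PGR by -3.08. Breast stem cell associated genes had a median of 0.56, or 0.09 with no filter on dim genes, with 3 of 16 higher, KLF4 (1.70), ITGA6 (1.24) and ITGB1 (1.19). The unfolded protein list had a median of 0.30 (0.49 after quantile normalization) with 7 of 18 higher. Mesenchymal genes had a median of 0.06 (73.4th percentile), up to 0.46 under other settings, with ITGA5 at 2.18. The basal list had a median of 0.72 over 5 genes, which became -0.05 when only brighter genes were kept.

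The pooled other fractions stood nearly as far from untreated cells as the unsorted PMA cells did. FBXO32 was at least 36.2-fold, IFIT1 at least 30.9-fold, DDX60 at least 16.0-fold, OAS1 at least 14.6-fold and ITGB6 30.2-fold higher, and MND1, SPC25, KIF15, CENPW and DIAPH3 differed by log2 -3.59, -3.36, -3.30, -3.29 and -3.26. SPC25, KIF15 and CENPW lay under the silent-family median of the pooled fractions. CD44 was 5.46-fold and CD24 4.45-fold higher. Of 11025 kept genes, 430 were higher and 641 lower at 2-fold, and 47 and 154 at 4-fold, with 14 higher and 6 lower among the 282 silent-family genes. Of the 56 silent-family genes that passed the filter 15 were past 2-fold (26.8%), against 9.71% of all kept genes. Cell cycle genes had a median of -1.92 (29 of 35 lower), interferon genes 1.59 (18 of 24 higher), proteases 1.09 (8 of 12 higher, 0.57 with no filter on dim genes) and integrins 0.73 (6 of 18 higher). Over 10826 genes, 273 were higher and 550 lower than untreated in both sorted samples, against 17.7 and 52.9 for independent lists and 0 and 0 in simulated unchanged arrays, and none went opposite ways. Both comparisons subtract the same untreated array, and 100 such simulated sets gave a Pearson r of 0.50 across genes where 0.89 was observed, and a covariance of 0.0157 against 0.468. The simulation does not include any departure of the untreated array itself, so part of the excess may come from that 1 array.

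Sorting itself was checked against the unsorted PMA cells. If sorting only separates cells, the unsorted level lies between the levels of the sorted samples. This held for 186 (84.5%) of the 220 genes that differed 2-fold between them. These genes were chosen for their gap between the sorted arrays, so a noisy level from another array would also often lie between. No share expected from noise was computed, so the 84.5% does not show that sorting only separated cells. Along the linear distance from the pooled fractions to the CD44-high CD24-low fraction, the unsorted sample lay at a median of 15.3% (quartiles 6.05% and 26.3%). None of 10810 genes had both sorted samples 2-fold above or 2-fold below the unsorted cells. That count could hardly be larger, since 1 of 10625 genes was past 2-fold between the pooled fractions and the unsorted cells. It also cannot show an effect of handling on the CD44-high CD24-low sample alone. The genes nearest to that size were RASD2, KCTD4, ANAPC1, GCAT and SAMTOR, where both sorted samples were higher by at least 0.70, 0.65, 0.64, 0.58 and 0.57 in log2. Both sorted samples were lower for CCDC88C, HSPA6, POM121L12, GLIS1 and SLC2A6, where the difference nearer 0 was -0.62, -0.60, -0.60, -0.59 and -0.53.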

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

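The tests of the silent families, of the overlap and correlation between comparisons, of the interferon list, of cyclic loess, of cell cycle phase and of carried-over cells were chosen after the results were seen, and the tests of the shares of PMA genes below or above the median and of the number of CD24 probes were set before. Signal appeared in probes that name several genes or no gene, which the gene counts leave out. Of such probes, 94 were 2-fold higher and 62 lower in unsorted PMA than in untreated cells, among 1494 bright enough. In the CD44-high CD24-low fraction against the pooled fractions the numbers were 4 higher and 14 lower of 1457. Against untreated cells they were 94 higher and 90 lower of 1478 for that fraction, and 86 higher and 64 lower of 1485 for the pooled fractions.

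Differences from the untreated array were wider than differences among the PMA arrays. Over 282 genes of silent families the SD of unsorted PMA minus untreated was 2.23 times that of pooled fractions minus unsorted PMA, as separate processing or hybridisation of the untreated array could produce. As the whole cause, that is argued against by comparisons that share no array. In these, 74 genes were lower in both where 6.91 would be shared by independent lists, and 29 were higher in both (3.31). In the opposite directions lay 0 and 13 genes, against 4.03 and 5.68 for independent lists. The 13 also exceeded their value, so the excess is weaker ground for genes higher with PMA. The correlation of these differences over all kept genes was too low to decide, with a smallest Pearson r of 0.138 over 4 scalings. A part played by culture, harvest or hybridisation cannot be told apart from PMA here, because 1 array stands for all untreated cells.

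Genes lower with PMA lay lower again in the CD44-high CD24-low fraction, in which 68.4% of 545 such genes were below the median difference (exact binomial interval 64.4 to 72.3%, which treats genes as independent). Cell cycle genes were lower in both comparisons, and the share was not computed without them. Whether it holds for other genes is therefore not shown. Intensity-dependent scaling of the arrays is argued against as the cause for the cell cycle list, whose median was -0.85 after cyclic loess. A gate that selects cells by size or cycle phase stays open, since the median of mitotic genes minus that of replication genes was -0.57, and no gate or phase data were at hand. Of 448 genes higher with PMA, 49.8% lay above the median (45.0 to 54.5%). That interval lies below the share set beforehand for a further rise but spans the share set against it, and it treats genes as independent. The test therefore decided neither. Of the 448 genes, 29 were 2-fold higher again and 13 were 2-fold lower. The interferon list had a median of -0.31 in the fraction (0.03rd percentile), which argues against a further rise of the list as a whole. Its members went both ways, with 3 of 25 2-fold higher and 2 lower. That the fraction carries the lower expression seen with PMA further is a candidate explanation from these arrays alone.

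CD24 transcript in the fraction sorted for low CD24 was 74.1% of that in the pooled fractions, and above the untreated level. If cells of the other fractions within the gate were the reason, and CD24-low cells held no CD24 transcript, no gene could lie below it. The 1141 genes that did may include array noise, since the ratio is a log2 difference of only -0.43. Of kept genes 133 were 2-fold lower, which under that premise argues against such cells as the whole cause. If CD24-low cells hold some CD24 transcript, the bound is lower and a part played by such cells stays open. A probe that reads other loci stays open, because the table held 1 CD24 probe. Control of the surface protein apart from its transcript may also apply and was not tested. The pooled sample also holds CD24-low cells, which would narrow the difference, and their share was not given in the sources used here.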

How the results depend on the processing

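The alternatives in this part were set before the data were examined, except that their use on the FOXO, NRF2 and antigen presentation lists was chosen after. Of 85 recomputed counts and shares, 74 stayed within 1.5 times the reported count or within the interval of the reported share, and 11 moved. The 3-fold threshold accounted for 10 of these by its own construction. It left 104 genes higher and 295 lower in unsorted PMA against untreated, 20 and 24 in the CD44-high CD24-low fraction against the pooled fractions, 146 and 368 in that fraction against untreated, and 101 and 250 in the pooled fractions against untreated. Under it the unsorted level lay between the sorted samples for 95.5% of genes, and 25 genes, in place of 103, differed the same way in the PMA and fraction comparisons. With no filter on dim genes, 1 gene in place of 0 had both sorted samples 2-fold on the same side of unsorted PMA, which comes from the dimmer genes let in. List medians moved by less than the distance from the middle to the edge of their random lists' central 95% in 537 recomputations, by more in 19, and in 1 a median outside that range changed sign, the basal list in the CD44-high CD24-low fraction against untreated, whose median was -0.047 under the 60th percentile filter. That filter keeps fewer of its genes. Medians inside that range changed sign in 28 recomputations, over 15 list comparisons. Over 426 named gene values the largest move was 0.36 in log2 under the 3 scalings and the mean of probes. Of the 238 past 2-fold none reversed and 14 fell under 2-fold in at least 1 of these settings. No paired analysis was possible because each group had 1 sample, and for the same reason no array could be left out. Signal over background limits dim genes, since silent families had a median of 3.37 in unsorted PMA cells and the lowest named levels lie near it.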

Other observations

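The gene groups in this part were picked after the largest differences had been seen, and their tests leave out the genes that prompted them. The tests of FOXO targets were chosen after some members had been seen on fixed lists, those of the other groups before the values of their remaining members were seen, and the recomputation under 6 other settings was chosen after. FBXO32, KLHL24 and TP53INP1, known targets of FOXO transcription factors, were higher in unsorted PMA cells by log2 5.30, 2.82 and 2.16. The remaining 17 measured FOXO targets had a median of 0.34 (98.3rd percentile of random lists), with 2 of them 2-fold higher, GADD45A and CCNG2, and none 2-fold lower. GADD45A, CDKN1B, SESN1 and BNIP3 also stand on the p53 or hypoxia lists, and without them the median over 13 genes was 0.35 (97.2nd percentile), inside the central 95%. Under 6 other settings these percentiles ran from 95.4 to 99.3 for the 17 genes and from 92.9 to 98.9 for the 13. Against untreated cells the wider list had a median of 0.39 in the pooled fractions (99.6th percentile, 99.0th without the genes of the fixed lists) and 0.23 in the CD44-high CD24-low fraction (93.9th percentile). Within the sort comparison it lay at the 24.0th percentile. A wider rise of FOXO targets was not decided, since these percentiles fell on both sides of the edge of the central 95%.

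B2M, TAP1 and PSMB9, which serve antigen presentation by class I molecules, were higher in unsorted PMA cells by 1.70, 1.03 and 0.63. The other 8 measured antigen presentation genes had a median of 0.42 (97.7th percentile, 96.6 to 98.3 under 6 other settings), and none was past 2-fold. Against untreated cells the median was 0.58 in the pooled fractions (99.5th percentile) and 0.37 in the CD44-high CD24-low fraction (92.9th percentile, inside the central 95%). Within the sort comparison it was -0.13, at the 18.7th percentile. A wider rise of antigen presentation genes was not decided by these values, since the percentile crossed the edge of the central 95% with the setting.

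AKR1C2 and SLC7A11, known targets of the oxidative stress factor NRF2, were higher in the CD44-high CD24-low fraction than in the pooled fractions by 2.66 and 1.14. The other 18 measured NRF2 targets had a median of 0.11 (94.8th percentile), inside the central 95% of random lists, the range set beforehand as speaking against a wider rise. That range does not decide it, because members went both ways, with 2 past 2-fold higher (GCLM 1.13 and GCLC 1.10) and AKR1B10 at -1.48, and because 3 of 6 other settings put the median above the range (percentiles of 94.6 to 99.3).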
